A study of Mus musculus with 5 samples.

How the data were processed

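Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of NKX2-1, a homeodomain transcription factor of lung epithelium, was carried out on whole lungs of wild-type mice at postnatal day 10. The labels describe 4 immunoprecipitations, each with another antibody against NKX2-1 (Abcam133737, Millipore07-601, Abcam76013 and Abcam133638), and 1 input library. Per the labels' protocol, lungs were fixed with formalin, nuclei were isolated and sonicated, and the chromatin was then pooled. All 4 file headers name the same input, so the libraries may share 1 chromatin preparation, and they are not independent animals as far as the labels tell. Each antibody has 1 library. No difference between antibodies therefore has a replicate check, no p-value is given between them, and values of all 4 libraries are set side by side.

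The deposited values used here are peak tables of the 4 antibody libraries. Per the file headers, the authors called peaks with MACS 2.1.2, separately for each antibody against the input, with a q cutoff of 0.05, an effective genome size of 1.87 Gb, 1 tag kept per position and the smaller library scaled up to the larger. Per the submitters' processing notes, FastQC, Trimmomatic, Bowtie, SAMtools, MACS2 and deepTools were used, with versions other than that of MACS not given in the sources used here, and the genome build was mm10. Per the file headers, each line holds an interval, its summit, the pileup signal at the summit in tags, a fold enrichment, which is a ratio over the local background, and a p-value and a q-value, both as −log10. The fold and the signal are the authors' values, and they serve only to describe, rank and filter peaks within a list, or to compare the libraries at the same regions after division by the number of filtered tags. Peaks lay on chromosomes 1 to 19, X and Y.

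Depth after the removal of duplicates was 46547989 tags for Abcam133737, 43031331 for Millipore07-601, 46472700 for Abcam76013 and 44777214 for Abcam133638, from 56489614, 53722468, 56201259 and 53543885 tags in total. In the input 50% of the tags were redundant, and its remaining tags were scaled up by 4.04 to 4.37. The local background of each peak, recovered from its pileup and fold with 1 tag added to each, was the genome-wide value for 60.0% to 63.3% of the peaks of a list and at most 1 input read (tolerance 0.02 reads) for 83.6% to 85.5%. For most peaks the input thus set no local level, and their fold is a pileup over a constant. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. The intervals of the median fold on chromosome X come from its regions, which are not independent replicates.

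Overlapping peaks of the 4 lists (at least 1 bp) were merged into regions, and each region was counted by the number of antibodies with a peak in it. A region with a peak of all 4 is called shared below. The overlap that chance gives came from 100 circular shifts of the lists along each chromosome. Regions were ranked by the mean over the 4 lists of the within-list percentile of fold enrichment, and the mean fold of a region is the mean of its 4 values. Genes were 21627 protein-coding genes on chromosomes 1 to 19 and X of the RefSeq annotation of GRCm38.p6, whose coordinates are those of mm10. That gene table gives the start and end of a gene without its strand or exons, so distances run to the nearer gene end, either the transcription start or the transcription end, where the design had named the transcription start. The split into exons and introns and the motif search, which need exons and sequence, were not run.

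The 14 gene lists (339 genes) were fixed before the data were examined. For each list, the number of genes with a shared region within 10 kb of a gene end was set beside 10000 random lists of the same size, matched on quintiles of gene length and of the number of genes within 100 kb. The percentile of the list among these describes these libraries and is not a test across animals. The random lists were drawn gene by gene and do not copy list members that lie side by side, such as Col4a3 and Col4a4. Percentiles of lists with such members may be too extreme, and their intervals too narrow. A list is called above or below the random lists at a percentile of at least 97.5 or at most 2.5. The named genes follow a rule fixed before the data were examined. It takes Nkx2-1, then from each list the 3 genes (5 for the alveolar type 1 and type 2 lists) whose best shared region within 10 kb has the highest mean percentile of fold, up to a pair of alveolar type 1 and type 2 genes without any peak (all of them had one), the 5 highest regions of the genome, and for each antibody the highest peaks that it alone gave. Other genes in the text were chosen after their values were seen.

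Alternatives set before the data were examined were a −log10 q-value of at least 5, a fold of at least 5, distinct intervals, a reciprocal overlap of 50%, summits within 100 bp, the 10000 peaks with the highest −log10 q-value of each list, the omission of each antibody, windows of 500 bp and 2 kb around gene ends, the midpoint of a region, distances of 2 kb and 50 kb, the gene nearest to each region up to 100 kb, each antibody on its own, and random lists without matching. Added after seeing the data were the gene body with 10 kb on each side, the 10000 strongest peaks for the gene lists, a background without predicted and chemoreceptor genes, the overlap of peaks at the genome-wide background, and 27 gene families chosen by symbol, of which 1 is not reported here.

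The scripts were tested on simulated data. With 8002 simulated sites found with all 4 antibodies, 8007 such regions came out, and an overlap share of 60.83% came out as 60.89%. For the real Abcam133737 and Millipore07-601 lists, bedtools 2.31.1 and the scripts both counted 38153 overlapping peaks. Among 200 simulated null lists of 25 genes drawn from the 21627 genes, 6% fell outside the random range, and of 200 lists with 85% of the members near a region, 84.5% came out above it. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.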

Results

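NKX2-1 binding was mapped in whole lungs of wild-type mice at postnatal day 10, an age at which the alveoli are forming. The alveolar epithelium consists of flat alveolar type 1 (AT1) cells, across which gas is exchanged, and cuboidal alveolar type 2 (AT2) cells, which make surfactant. The series title places the data in a study of how NKX2-1 controls the development and maintenance of AT1 cells. This tissue was immunoprecipitated with 4 antibodies against NKX2-1, with 1 library each at 43031331 to 46547989 filtered tags, beside 1 input library. The peak lists held 40877 peaks for Abcam133737, 57763 for Millipore07-601, 41296 for Abcam76013 and 57891 for Abcam133638, with median lengths of 257, 277, 260 and 264 bp. They covered 12.1, 18.7, 12.3 and 18.2 Mb of the genome, and their median fold enrichments, as the authors' caller gave them, were 5.35, 5.92, 5.28 and 5.82. With 1 library per antibody, none of the values below has a replicate error.

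The Nkx2-1 gene itself carried 6 regions called with all 4 antibodies within 10 kb of its ends. The strongest lay inside the gene (mm10, chromosome 12, 56534904 to 56535744) at a fold enrichment of 20.1 with Abcam76013, 21.0 with Abcam133737, 26.0 with Millipore07-601 and 26.9 with Abcam133638. Both AT1 and AT2 genes carried stronger regions than this. The region with the highest fold near a gene of the lists lay inside Col4a4 and 8.53 kb from Col4a3, a pair of neighbouring genes for basement membrane collagen chains (chromosome 1, 82577779 to 82578386). Its fold was 38.1 to 53.1 in the 4 libraries. Near Sftpc, the surfactant protein C gene of AT2 cells, the strongest region lay 5.60 kb away inside the neighbouring gene Lgi3 (chromosome 14, 70529684 to 70531106), with folds of 27.0 to 42.9. Peaks of all 4 antibodies also spanned an end of Sftpc itself, with folds of 16.2 to 21.7.

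**Figure D1:**
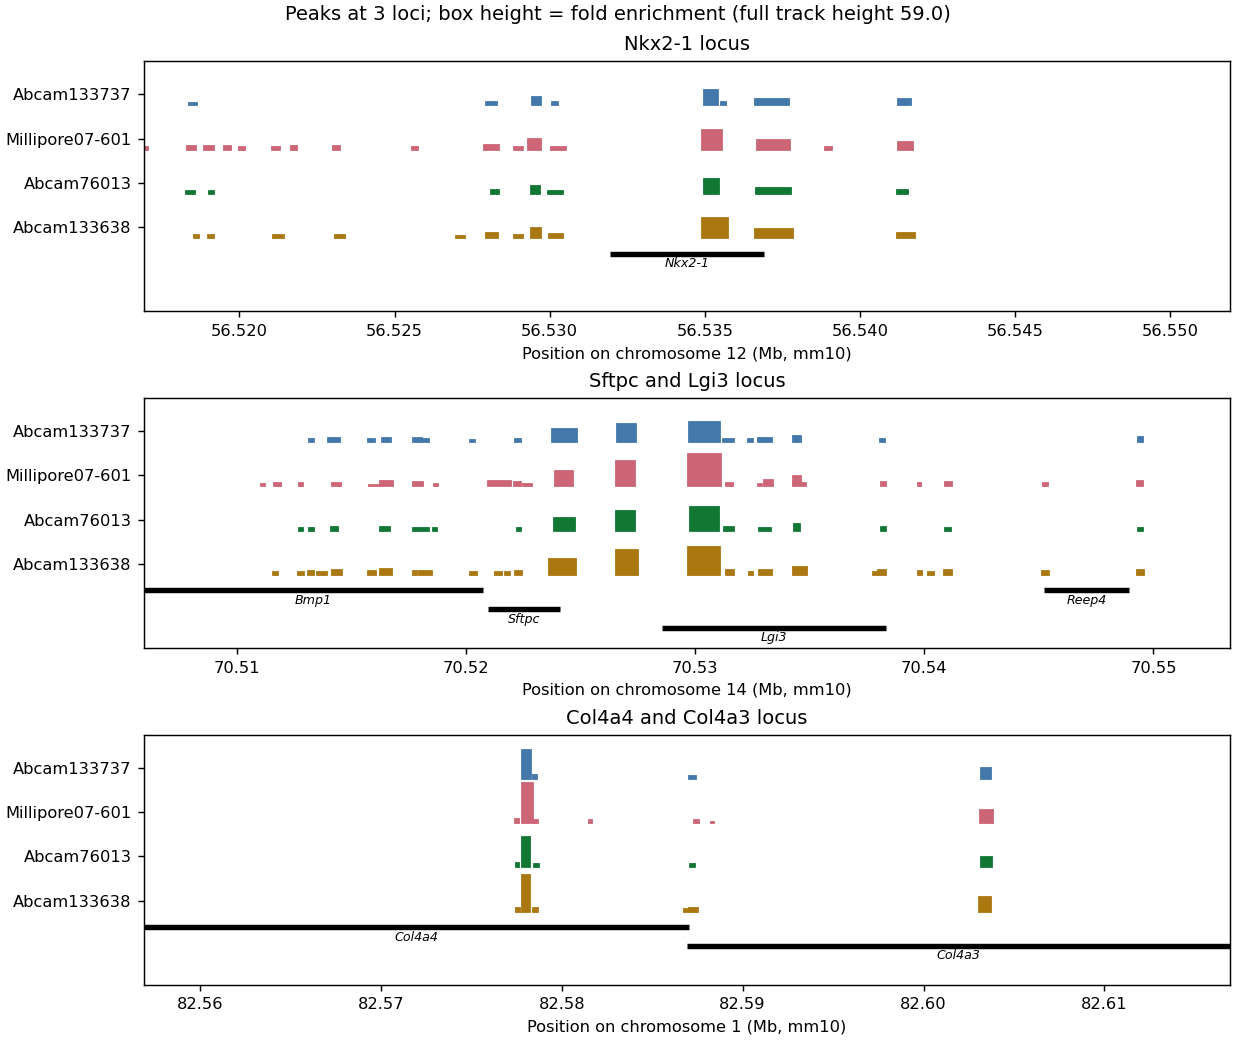
Peaks of the 4 antibodies at the Nkx2-1, Sftpc/Lgi3 and Col4a4/Col4a3 loci against position in Mb (mm10), with genes as black bars; each box is a peak and its height is the fold enrichment, on a scale of 59.0 per track. The tallest boxes stand at the same positions in all 4 tracks, inside Nkx2-1, inside Lgi3 and inside Col4a4.

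The first comparison asks how far the 4 antibodies mark the same places. Merging the lists gave 68919 regions, of which 31606 (45.9%, interval 45.5 to 46.2) had a peak of all 4 antibodies, 9284 of 3, 10634 of 2 and 17395 of 1. Circular shifts of the lists gave a mean of 0.39 regions with all 4, and at most 4 in 100 shifts. The highest-ranked shared regions of the genome lay inside Slc26a9, which encodes a chloride transporter (chromosome 1, 131763872 to 131765115, mean fold 51.05), inside Atf6, which encodes a transcription factor of the unfolded protein response (chromosome 1, 170770486 to 170771157, mean fold 49.6), and inside Tnrc6a (chromosome 7, 123097478 to 123098565, mean fold 48.2). Another lay outside genes at 10.7 kb from Mycbp (chromosome 4, 123893656 to 123894275, mean fold 48.2), and 1 lay outside genes at 50.0 kb from Nrep (mean fold 48.8).

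Between antibodies, 64.9% to 93.9% of the peaks of a list overlapped a peak of another list, over the 12 ordered pairs, against 1.00% to 1.52% on average after shifting. Where peaks overlapped, the median distance between summits was 23 to 24 bp, and 91.7% to 93.6% of summits lay within 100 bp of a summit of the other list. Across the 31606 shared regions, Spearman's rho of the fold between any pair of antibodies was 0.83 to 0.86. Regions are not independent replicates, and the libraries may share 1 chromatin preparation and do share the input, so this measures the likeness of these libraries. Among the regions called with 2 antibodies, 6783 of 10634 (63.8%) combined Millipore07-601 and Abcam133638, the antibodies with the longer lists, and 149 (1.40%) combined Abcam133737 and Abcam76013.

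**Figure D2:**
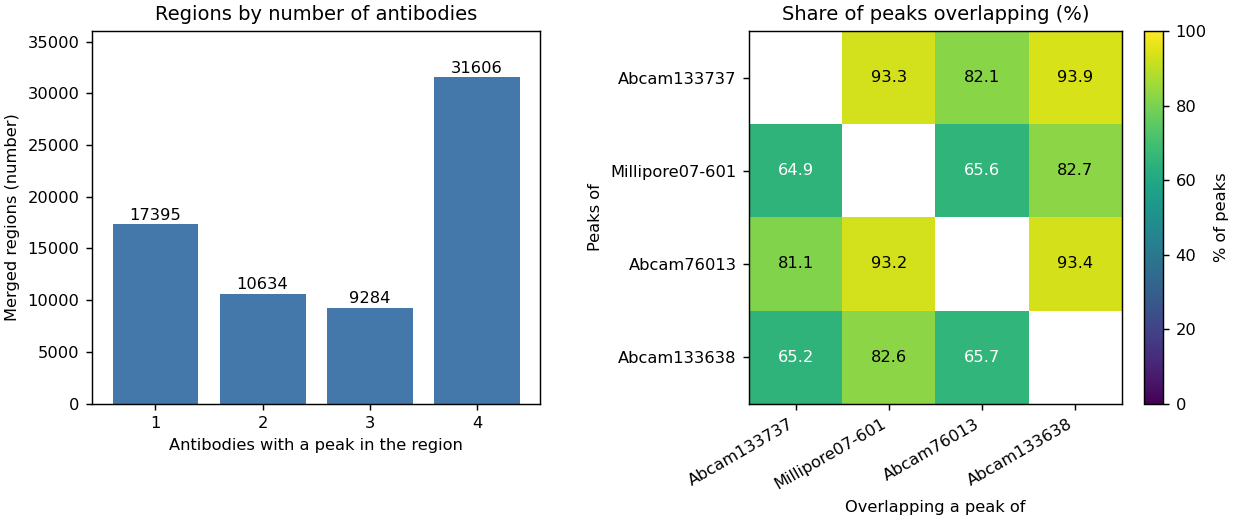
Left, the number of merged regions by the number of antibodies with a peak in them, from 17395 with 1 to 31606 with 4. Right, the percentage of the peaks of each antibody (rows) that overlap a peak of another (columns), from 64.9% to 93.9%; the low values are those of the longer lists against the shorter ones.

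Shared regions held the strong peaks of each list. The median fold of peaks in shared regions against peaks called with 1 antibody alone was 5.96 against 3.54 for Abcam133737, 8.33 against 4.02 for Millipore07-601, 5.89 against 3.65 for Abcam76013 and 8.19 against 4.10 for Abcam133638. Of the peaks in shared regions, 93.5%, 95.6%, 91.4% and 95.4% in the same order lay above the median of those called alone. Of the 10% of peaks with the highest fold in each list, 100%, 100%, 100% and 99.98% were in shared regions, and of the lowest 10%, 47.0%, 13.95%, 47.0% and 13.0%. Peaks called alone made up 2.498%, 13.4%, 2.63% and 13.1% of the lists. Each list was cut at the same q-value, and weak peaks near a cutoff are more easily missed in another list. The contrast in fold was therefore partly fixed by the calling.

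The strongest peaks given by 1 antibody alone were weaker than the best shared regions. With Abcam133638 they lay inside Ctdspl2 (chromosome 2, 121956265 to 121956531, fold 14.03) and inside Nfkb2 (chromosome 19, 46305456 to 46305786, fold 10.3). With Millipore07-601 they lay 29.8 kb from Lrpap1 (chromosome 5, 35135479 to 35135663, fold 8.66) and inside Fkbp15 (chromosome 4, 62353579 to 62353804, fold 8.46). With Abcam133737 the highest fold was 5.76, on chromosome 12 at 675 kb from Zfp386 (115372183 to 115372437), followed by 5.56 beside Srp54b (55189242 to 55189441). With Abcam76013 it was 5.59, inside Rnf43 (chromosome 11, 87710724 to 87710944), followed by 5.48 at 2.72 kb from Gtf2a1 (chromosome 12, 91552295 to 91552541).

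**Figure D3:**
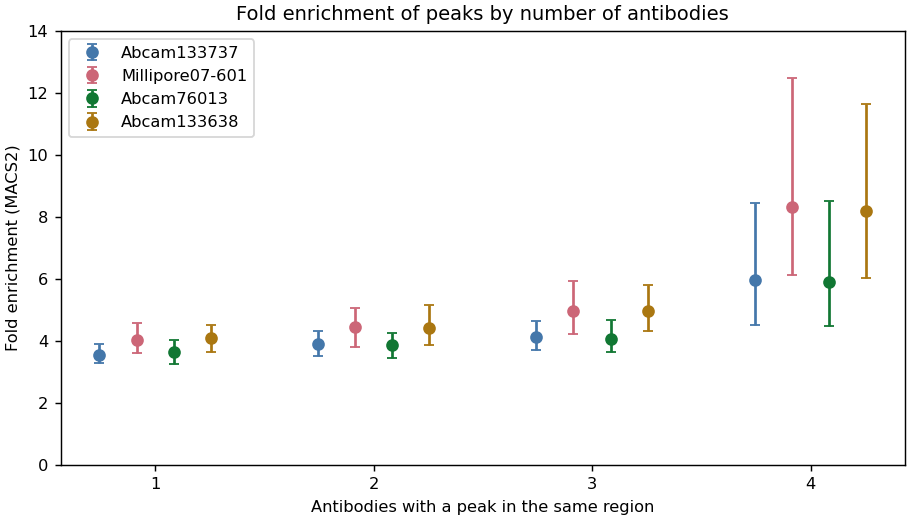
Fold enrichment of the peaks of each antibody (vertical axis, as MACS2 gave it) by the number of antibodies with a peak in the same region (horizontal axis); points are medians and bars run from the first to the third quartile. The medians lie between 3.54 and 4.10 for peaks called alone and between 5.89 and 8.33 for peaks shared by 4.

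Next, the position of the shared regions relative to genes was described. By their summits, 22.5% (interval 22.0 to 22.9) lay within 1 kb of a gene end, against 3.23% after shifting, 47.1% lay further inside a gene, against 39.4%, and 30.4% lay outside genes, against 57.4%. The 10% of shared regions with the highest fold percentiles had fewer summits near gene ends, 11.2% (10.1 to 12.4), and more inside genes, 54.5% (52.7 to 56.2). Regions called with 1 antibody had 18.5% near gene ends, 49.3% inside and 32.2% outside genes. The median distance of a shared region to the nearest gene end was 10.5 kb, 49.2% lay within 10 kb and 20.4% over 50 kb away.

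Genes of both alveolar cell types were close to shared regions. Whole lungs mix cell types, so the cells in which a region was bound, AT1, AT2 or other, cannot be told. The fold of a region may also depend on how common those cells are. A shared region lay within 10 kb of a gene end for 26 of 30 AT1 genes (86.7%, interval 69.3 to 96.2) and 29 of 30 AT2 genes (96.7%, 82.8 to 99.9), against means of 17.1 and 16.2 genes in matched random lists, and 54.7% of all protein-coding genes. Of the 10000 random lists of each kind, 95% held 12 to 22 and 11 to 21 such genes. The AT1 list lay at percentile 99.98 and the AT2 list at 100. The intervals of both lists overlap, and the difference between them was not tested. All 30 AT1 and all 30 AT2 genes had a peak of at least 1 antibody within 10 kb.

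The strongest regions near AT1 genes, after the one that Col4a3 and Col4a4 share, lay inside Icam1, an adhesion molecule gene (chromosome 9, 21024976 to 21025705, mean fold 39.0), 5.51 kb from Akap5 and inside its neighbour Mthfd1 (chromosome 12, 76318477 to 76319109, mean fold 38.5), and inside Cyp4b1 (chromosome 4, 115645228 to 115645835, mean fold 31.7). Widely used AT1 markers ranged below these. The best regions had mean folds of 27.6 near Cldn18, 24.1 at the end of the water channel gene Aqp5, 19.2 in Ager, 17.7 in Cav1 and 5.38 in Hopx. The AT1 genes without a shared region within 10 kb were Igfbp2, Lmo7, Myrf and S100a6. Over the AT1 genes with one, the median of the best mean fold was 13.7.

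The strongest region near an AT2 gene spanned an end of Cxcl15 (chromosome 5, 90794021 to 90794916, mean fold 41.3). The region shared by Sftpc and Lgi3 followed at 34.7, then one 9.31 kb from Muc1 that lay inside Thbs3 (chromosome 3, 89218209 to 89219745, 32.8) and one 1.59 kb outside Etv5, an ETS transcription factor gene (chromosome 16, 22441161 to 22441803, 32.5). Best regions had mean folds of 29.5 in Napsa, 27.1 at Sftpb, 27.1 near Cebpa and 17.2 in Abca3, the lipid transporter gene of lamellar bodies. Lyz2 was the AT2 gene without a shared region. The median of the best mean fold over AT2 genes was 17.2.

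General epithelial genes were also close to shared regions, with 28 of 30 (93.3%, 77.9 to 99.2) against a random mean of 14.7 and at percentile 100. Their strongest regions lay inside Esrp2, a splicing regulator gene (chromosome 8, 106134904 to 106136042, mean fold 24.8), in Nkx2-1 (23.5) and inside the claudin gene Cldn7 (chromosome 11, 69965200 to 69965688, 19.3). The E-cadherin gene Cdh1 had a best region of mean fold 12.6 and Epcam one of 8.42, and Ehf and St14 had none. Genes tied to the YAP and TEAD transcriptional regulators numbered 22 of 26 (84.6%, 65.1 to 95.6) against 14.2, at percentile 99.96. Their strongest regions lay inside Wwc1 (chromosome 11, 35970485 to 35971847, mean fold 29.6), 0.678 kb from Axl and inside its neighbour Hnrnpul1 (chromosome 7, 25754490 to 25755822, 20.7) and inside Amotl2 (chromosome 9, 102717406 to 102717905, 18.7). Shared regions also stood near Tead1, Tead4, Yap1 and Wwtr1, at mean folds of 10.9, 12.7, 7.62 and 7.37.

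Of both airway lists, that of secretory cells lay above the random lists. Secretory cell genes numbered 11 of 15 (73.3%, 44.9 to 92.2) against 6.59, at percentile 99.2, and ciliated cell genes 12 of 15 (80%, 51.9 to 95.7) against 8.58, at percentile 96.5 and so within the random range. The secretory list came within the random range with 2 kb (8 genes against 4.75, percentile 96.1), without matching (92.23) and with a background without predicted and chemoreceptor genes (94.97). The ciliated list came above it with the peaks of Millipore07-601 (99.81) or Abcam133638 (99.70) alone and with the nearest gene (97.63). The strongest secretory regions were 9.94 kb from Aldh3a1 and inside Aldh3a2 (chromosome 11, 61228361 to 61228819, mean fold 22.2), 1.90 kb from the club cell secretoglobin gene Scgb1a1 (chromosome 19, 9081046 to 9081747, 19.7) and 2.49 kb from Lypd2 but nearer Slurp1 (chromosome 15, 74729188 to 74729753, 19.1). Those of the ciliated list were 5.65 kb from Tppp3 and inside Lrrc36 (chromosome 8, 105461238 to 105461843, 34.0), inside Dynlrb2 (chromosome 8, 116508533 to 116509695, 28.0) and beside Mcidas (chromosome 13, 113000568 to 113001159, 16.5). Foxj1, the regulator of motile cilia, had none.

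Genes of other lung cell types were less often close to shared regions than random genes, except those of endothelium. Mesenchymal genes numbered 7 of 27 (25.9%, 11.1 to 46.3) against 14.5, at percentile 0.17, and immune genes 7 of 28 (25.0%, 10.7 to 44.9) against 15.2, at percentile 0.05. Pdgfra, Fgf10, Tbx4, Tcf21, Ptprc, Csf1r and Marco were among those without a shared region. Endothelial genes numbered 13 of 25 (52.0%, 31.3 to 72.2) against 13.7, at percentile 39.3. Within 2 kb the count was 2 of 25 against 9.73, at percentile 0.05, and Cdh5, Kdr and Tie1 had no peak of any antibody within 10 kb. The mesenchymal list came within the random range with 50 kb (percentile 12.1) and the nearest gene (2.72), and the immune list with 50 kb (13.07) and the 10000 strongest peaks (7.46).

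Some of the strongest regions of these lists were nearer another gene, as were those of Akap5 and Muc1 in the alveolar lists. Near mesenchymal genes they lay 3.10 kb from Myocd (chromosome 11, 65170132 to 65170507, mean fold 18.8), inside Pdgfrb (7.61) and inside Notch3 (chromosome 17, 32162566 to 32162822, 5.50). Near immune genes they lay 6.69 kb from Cd79a but 0.232 kb from Rps19 (chromosome 7, 24890043 to 24890806, 29.5), 7.81 kb from Cd14 at an end of Tmco6 (17.1) and 5.08 kb from Cd68 inside Eif4a1 (chromosome 11, 69671247 to 69671672, 9.62). Near endothelial genes they lay 0.835 kb from Esam but nearer Msantd2 (chromosome 9, 37526710 to 37527254, 18.5), 4.79 kb from Car4 (chromosome 11, 84952517 to 84952961, 16.2) and 5.11 kb from Gpihbp1 (chromosome 15, 75603321 to 75603741, 16.3).

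Genes of other organs in which NKX2-1 acts, or whose programme differs from that of the lung, were also seldom close. Gastrointestinal genes numbered 6 of 25 (24.0%, 9.36 to 45.1) against 13.4, at percentile 0.11, and neural genes 6 of 26 (23.1%, 8.97 to 43.6) against 12.8, at percentile 0.17. The gastrointestinal list holds neighbouring Gkn, Tff and Muc genes, which are not independent, so its percentile may be too extreme. Thyroid genes numbered 3 of 12 (25.0%, 5.49 to 57.2) against 6.87, at percentile 1.28. The thyroid call was lost with 2 kb (percentile 3.84), with 50 kb (10 of 12 genes, 69.9), without Abcam133737 (3.02), with each antibody on its own (6.13 to 34.77) and with the 10000 strongest peaks (4.60). The gastrointestinal call was lost with 50 kb (8.82), with Abcam133638 on its own (4.77) and with the strongest peaks (4.23), and the neural call with the strongest peaks (3.84). The strongest gastrointestinal regions lay inside Reg4 (chromosome 3, 98227753 to 98228140, mean fold 14.5) and at Gkn3, which shares it with Gkn2 (chromosome 6, 87388883 to 87389210, 8.14). In the thyroid list they lay at an end of the thyrotropin receptor gene Tshr (chromosome 12, 91400759 to 91401087, 11.8), 8.995 kb from the iodide transporter gene Slc5a5 at an end of Ccdc124 (chromosome 8, 70873377 to 70873890, 11.3) and at an end of the thyroglobulin gene Tg (chromosome 15, 66670491 to 66670804, 6.07). In the neural list they lay inside Gfap (chromosome 11, 102892934 to 102893305, 18.1), 1.01 kb from Camk2a (9.90) and 9.22 kb from Slc17a7 at an end of Aldh16a1 (chromosome 7, 45154197 to 45154703, 8.47).

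Housekeeping genes, active in all cells, were close to shared regions in 23 of 25 cases (92.0%, 74.0 to 99.0) against 13.5, at percentile 100, and proliferation genes in 20 of 25 (80%, 59.3 to 93.2) against 14.5, at percentile 99.1. Their regions were weaker than those of the alveolar lists, with medians of the best mean fold of 7.37 and 7.00. Restricted to the 10000 strongest peaks of each antibody, 4 housekeeping and 3 proliferation genes remained close to a shared region, at percentiles 46.4 and 22.0, while 19 AT1, 18 AT2 and 18 general epithelial genes did, all at percentile 100. The proliferation list also came within the random range with 2 kb (15 genes against 10.5, percentile 96.3) and with a background without predicted and chemoreceptor genes (97.10). The strongest regions were at an end of Rplp0 (chromosome 5, 115559241 to 115559600, mean fold 15.0), 8.48 kb from Eef2 at an end of Pias4 (chromosome 10, 81167598 to 81168150, 14.8) and 4.62 kb from Sdha at an end of Pdcd6 (chromosome 13, 74317179 to 74317634, 13.0). For proliferation genes they were 3.28 kb from Mcm2 at an end of Tpra1 (chromosome 6, 88902063 to 88902943, 18.6), 7.51 kb from Bub1 at an end of Mtln (chromosome 2, 127792262 to 127792686, 16.5) and 3.89 kb from Cdc20 inside Elovl1 (chromosome 4, 118428551 to 118429015, 10.4), a gene of the AT2 list.

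**Figure D4:**
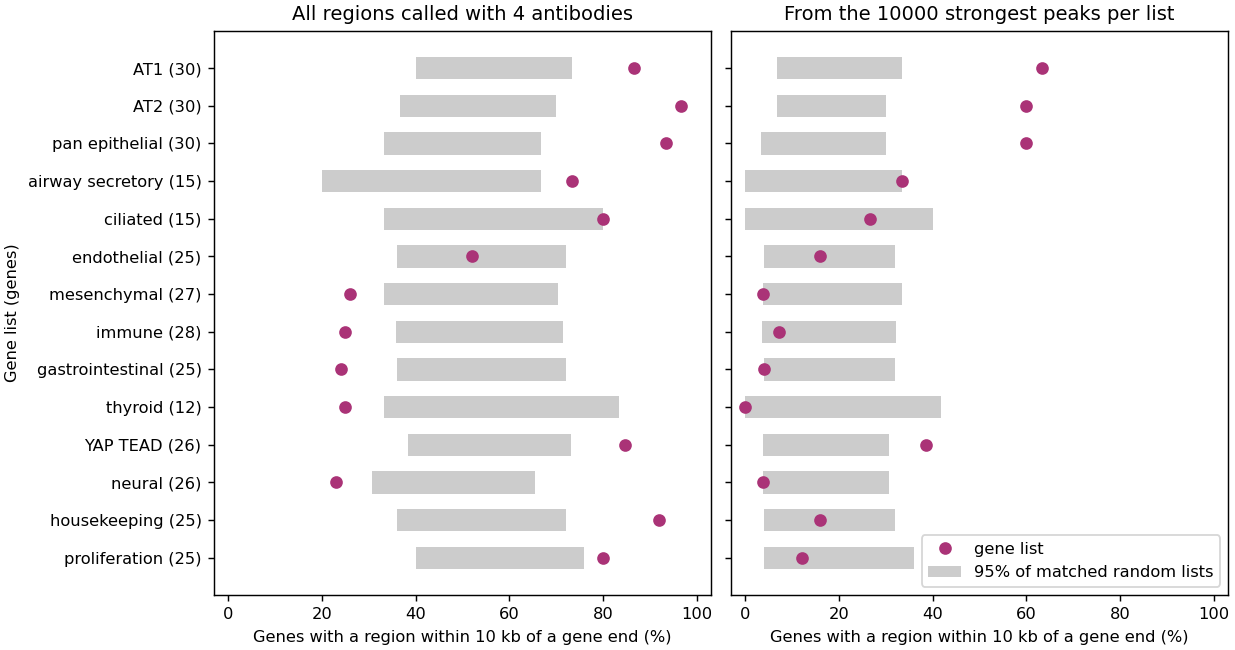
Percentage of the genes of each list (number of genes in brackets) with a region called with all 4 antibodies within 10 kb of a gene end, from all peaks (left) and from the 10000 strongest peaks of each antibody (right); grey bars span 95% of the matched random lists. The AT1, AT2, general epithelial and YAP/TEAD points lie beyond the grey bars in both panels, and the housekeeping point (92.0%, left) lies within them on the right.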

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

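The overlap of peaks at the genome-wide background, the gene body with 10 kb on each side, the 10000 strongest peaks for gene lists and the background without predicted and chemoreceptor genes were chosen after the data had been seen, and the other alternatives before. The AT1, AT2, general epithelial and YAP/TEAD lists lay above the random range under all 15 alternatives (lowest percentiles 99.94, 100, 100 and 99.5), the housekeeping list under 14 and the secretory and proliferation lists under 12 each. The mesenchymal and immune lists lay below it under 13, the neural under 14, the gastrointestinal under 12 and the thyroid under 7. Limits are the single library per antibody, the shallow input, scaled up by at least 4.04, and distances to gene ends without strand. The lists hold 12 to 30 genes, so their intervals are wide, and some of their members lie side by side. Binding in whole lung cannot be assigned to a cell type. The motif and exon alternatives were not run. The cause of the changes below was not tested, except that stricter thresholds keep fewer peaks by construction.

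A fold of at least 5 left 22362 (Abcam133737), 36415 (Millipore07-601), 22615 (Abcam76013) and 35804 (Abcam133638) peaks and 17884 shared regions, and the 10000 strongest peaks left 7342 shared regions. The lowest and highest pairwise overlap were 59.32% and 84.31% with a reciprocal overlap of 50%, 60.76% and 86.06% with summits within 100 bp, 83.99% and 85.51% with the 10000 strongest peaks, 62.01% and 95.50% with a −log10 q-value of at least 5, and 66.16% and 93.59% for peaks at the genome-wide background. Peaks in shared regions above the median of those called alone came to 93.11% (Abcam133737), 93.33% (Abcam76013) and 96.93% (Abcam133638) by −log10 q-value, and to 97.36% (Millipore07-601), 93.73% (Abcam76013) and 96.99% (Abcam133638) with summits within 100 bp. The shares near gene ends, inside and outside genes were 18.06%, 50.06% and 31.89% with 500 bp, 28.25%, 43.33% and 28.42% with 2 kb, and 18.49%, 49.32% and 32.19% for regions of 1 antibody.

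In percentage points over the random mean, the nearest gene gave 39.30 for AT1, 47.43 for AT2 and 53.41 for general epithelial genes, 50 kb gave 26.23 for AT2 and −8.88 for immune genes, and 2 kb gave 51.25 for general epithelial, 45.50 for housekeeping and −30.93 for endothelial genes. The 10000 strongest peaks gave 44.93 for AT1. Direction was reversed for thyroid genes with 50 kb (6.71) and, with the 10000 strongest peaks, for housekeeping (−1.07) and proliferation genes (−6.23).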

Other observations

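The gene families, the chromosome comparison, the dense windows and the tests of depth, of enrichment, of neighbouring genes and of rarely bound X genes were chosen after the results had been seen. The tests of separate strong sites, of weak promoter signal and of X copy number had their bounds set before their own values were known. The bound for X copy number was, however, taken from the ratio of X to the lowest autosome, which had already been seen.

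Among 27 gene families picked by symbol, 7 lay above and 8 below the matched random lists. These lists were drawn gene by gene, so they do not copy families whose members lie side by side. Such members are not independent, and the percentiles of their families may be too extreme. Only Hoxb1 of 39 Hox genes, the regulators of position along the body axis, had a shared region within 10 kb, against a random mean of 20.0, and this was below all 10000 random lists. Of 23 cadherin genes with a numbered Cdh symbol, 4 had one (Cdh1, Cdh3, Cdh16 and Cdh24) against 12.5, at percentile 0.01, but with the 10000 strongest peaks the count of 3 against 3.82 lay at percentile 34.7. Olfactory receptor genes had 20 of 1106 against 398.5, vomeronasal receptor genes 5 of 353 against 131.6 and beta-defensin genes 2 of 42 against 17.9, all below every random list. At the other end, Kruppel-like factor genes had 13 of 17 against 8.05 (percentile 99.3) and ETS factor genes 16 of 21 against 11.6 (percentile 97.53). With the 10000 strongest peaks both came within the random range, at 2 against 2.43 (percentile 41.4) and 6 against 3.61 (percentile 90.4).

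Shared regions also crowded at a few loci. The window of 200 kb with the most held 34 at Irf2bpl and Cipc (chromosome 12, summits from 86772219 to 86968676), followed by 33 from Cnn2 to Cirbp (chromosome 10, 79985038 to 80167737) and 30 around Sfi1 and Patz1 (chromosome 11, 3124019 to 3302979). Windows from Tlcd2 to Myo1c, at the keratin genes Krt8 and Krt18 and at Sftpb held 28 each, and windows from Gpam to Acsl5, at the sodium channel gene Scnn1a and at Napsa 27 each. Keratin genes as a family were below every random list, again drawn gene by gene, with 15 of 53 against 32.2. With the 10000 strongest peaks they came within the random range (7 against 10.4, percentile 11.7). In 20 random placements of the shared regions the highest window held 15. The named windows held 2 to 11 genes and were not compared with others of like gene number. No filter for multi-copy or high-signal stretches of the genome was applied here, and the input set no local level for most peaks. Extra copies of a stretch, around Sfi1 or elsewhere, are therefore not excluded. The cause of the crowding was not tested.

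The longer peak lists of Millipore07-601 and Abcam133638 do not follow sequencing depth, since their libraries had fewer filtered tags on average, 0.944 times those of the shorter lists. As a class, the regions called with both of these antibodies only were not as strong as the rest. These 6783 regions had median within-list fold percentiles of 24.79 and 26.0, below the bound of 40. A median does not exclude a minority of strong sites seen by these antibodies only. At shared regions their pileup relative to the number of filtered tags was 1.324 to 1.49 times higher, which is consistent with weaker enrichment in the libraries of the shorter lists. Whether this comes from the antibodies or from the handling of each immunoprecipitation stays open, since each has 1 library.

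Shared regions at housekeeping genes are not explained by sites of neighbouring genes alone, as within 2 kb the list stayed at percentile 100. With the 10000 strongest peaks it came to percentile 46.39 while the AT1 and AT2 lists stayed at 100, and a candidate explanation is weak signal that open promoters give in any immunoprecipitation. With the strongest peaks within 10 kb, ribosomal protein genes (16 of 80 against 9.01) stayed above the random lists, at percentile 98.8. So did NADH dehydrogenase genes picked by the Nduf symbol (15 of 49 against 7.43), at 99.7. Proteasome genes (4 of 39 against 7.07) did not, at 9.97. The 2 kb distance was not applied to these families, so sites of neighbouring genes may be counted. These values therefore do not decide whether open promoters account for all such genes. Weak but real binding of NKX2-1 at these promoters was not tested and stays open, because no immunoprecipitation with a control antibody was analysed here.

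Chromosome X had few shared regions, 374, or 38.7 per 100 genes against 102.0 to 212.4 on the 19 autosomes, at a median fold of 6.93 against 7.00 to 7.29. Predicted and chemoreceptor genes do not account for it. Without them, 19.74% of X genes were near a shared region, against 53.71% on the lowest autosome. Other rarely bound gene families on X were not taken out, so their part stays open. Halving the pileups of 31231 autosomal regions, as 1 copy of X in males could, left 60.25% at or above the smallest called pileup in all 4 libraries at a median fold of 4.79, below the interval of the X median (6.53 to 7.38), while X had 37.9% of the regions per gene of the lowest autosome and 24.97% of the median one. With all regions held to the 10th or 25th percentile of called pileups, thresholds added after that value was seen, the halved folds of 6.08 and 6.89 stayed below the X intervals (6.65 to 7.49 and 7.39 to 8.19), and 38.02% and 33.0% were left, above X against the median autosome (25.2% and 23.9%) but not against the lowest (38.3% and 36.5%). The halved folds and the shares set against the median autosome argue against copy number as the whole cause. Set against the lowest autosome, the share does so only at the smallest called pileup, so that comparison depends on the threshold. A partial effect of copy number stays open, as do fewer sites on X, which was not tested. The labels used here do not give the sex of the animals, and 6 regions lay on Y, 1 of them shared.

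For peaks called with 1 antibody alone, a pair of tests of chance calls against sites that 1 antibody sees was also run and decided nothing. Such peaks made up 2.498% to 13.4% of a list, where chance calls had been predicted to stay at or below 5%. The genome-wide background was the local level of 65.5%, 54.7%, 68.3% and 62.6% of them for Abcam133737, Millipore07-601, Abcam76013 and Abcam133638, and of 63.2%, 62.1%, 62.6% and 63.4% of the peaks in shared regions.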
